A study of Arabidopsis thaliana with 12 samples.

How the data were processed

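RNA from 12 libraries of Arabidopsis thaliana seedlings was analysed: 4 groups (Col-0 and 35S:miR396a, each dark or illuminated for 3 h) of 3 libraries that the labels call biological replicates. Per the labels, the plants were kept dark for 4 days on MS medium to which sucrose (1%) was added. The letters D and L of the sample titles were read as dark and light from the labels' treatment protocol. Per the labels' protocols, total RNA was extracted, messenger RNA libraries were built and these were sequenced on the BGISEQ-500 platform. Strand and layout of the libraries are not given in the sources used here. Per the series' design text and the submitters' processing notes, reads were mapped with HISAT and Bowtie2 to TAIR10; versions are not given in the sources used here.

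The values come from 6 tables, one per pair of groups. Per the file headers, each table holds the mean FPKM of both groups, a log2 fold change and a q-value and p-value of DEGseq. The FPKM columns are group averages made by the authors. The deposited log2 fold change is that of the second group over the first, which was checked on the sign of the FPKM ratio. The deposited q-value and p-value are those of DEGseq per the file headers, while the design text names NOISeq with a 2-fold difference and a probability above 0.8, so the text and the headers disagree on the tool. In every table each gene has a log2 fold beyond 1 in size and a q-value under 0.001, so the tables hold called genes only. The largest p-value of a listed gene was 0.00217 to 0.0051 per table, above the largest q-value. A q-value under 0.001 is therefore not stricter here than a p-value under 0.001. A group value was found in any table that lists the gene, and the values of a group differed between tables for 0 genes. Columns of other series numbered 0.

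The design fixed before the data were examined allowed for tables of single libraries; because the tables hold group averages, no model was fitted and the authors' deposited calls were counted instead. The deposited folds and p-values were checked against DEGseq's random-sampling model on reads pooled over the 3 libraries of a group. Pooled reads solved from the fold and p-value came out whole within 0.05 for 81.8% to 85.8% of genes with few reads (302 to 576 genes per table). The deposited p-values therefore carry counting error only, and the spread between the replicates does not enter them. Pooled depth, from reads, FPKM and transcript length of 489 to 672 genes per group with transcripts of at least 1500 bases, had a median of about 115000000 fragments for dark Col-0, 119000000 for illuminated Col-0, 119000000 for dark 35S:miR396a and 128000000 for illuminated 35S:miR396a. Calls resting on under 30 pooled reads in the larger group numbered 208 for light in Col-0, 269 for light in 35S:miR396a, 122 for genotype in the dark and 300 for genotype in the light, among genes with a p-value above 0. Folds against a value of 0 are not given, since an exact 0 can be a failed estimate.

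Gene identifiers were matched to the TAIR10.1 reference annotation, from which symbols and positions were taken. Of the 11417 genes listed in any table, 11157 identifiers matched, 134 were new transcripts named by the sequencing centre and 126 matched neither. Values in all 4 groups were known for 6223 genes.

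Before the data were examined, 20 gene lists with 371 members were fixed: miR396 targets, other members of the miR396 module, tetrapyrrole synthesis, light-harvesting antenna, photosystems and Rubisco, light signalling, circadian clock, flavonoid synthesis, antioxidants, oxidative-stress markers, heat shock, brassinosteroid, auxin, cell-wall expansion, gibberellin and ethylene, jasmonate and defence, cell cycle, and markers of seed reserves, roots and the shoot apex. For each list and main comparison, members listed higher and lower were counted. Members listed in no table (all but 303 of the 371) were left out of the share tested. The share among the rest was compared with that of all genes listed in any table by Fisher's exact test, two-sided. Adjustment was by Benjamini-Hochberg over 80 tests, with 0.05 as the threshold, and 26 passed. A test of the split between higher and lower against other listed genes of the same table was added after the data were seen, and 28 of 76 passed. These tests run across genes, which are not replicates. A count adjusted over the list alone could not be made, since the tables hold called genes only. A list of 20 rapid touch and wound genes was added after the data were seen.

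The difference of the light effect was computed as log2(FPKM + 1) light over dark in 35S:miR396a minus that in Col-0. Overlaps of lists were set beside n1 × n2 / N with the genes listed in any table or all 38095 annotated genes as N. The light tables share no libraries, nor do the genotype tables. Named genes follow a rule fixed before the data were examined: the 5 largest folds in each direction per main comparison among genes whose larger mean was at or above the median, every member of the miR396 lists, up to 3 members with the largest fold of each other list with 3 or more listed members, the 3 largest differences of the light effect in each direction, and every gene of a count of 5 or fewer, which were chosen after their values were seen. Not every gene that the rule picked is named below, and the choice among them was made with their values known. CPD, CHS and PHYA, and values of a named gene in a comparison other than the one that named it, were chosen after their values were seen.

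Alternatives were a 4-fold threshold, a q-value of 1e-10 or less, a filter on low values, FPKM ratios with a pseudocount of 1 (or 10 for the difference), recentred ratios and other backgrounds; those added after the data were seen were at least 30 pooled reads, no organelle genes, a background of genes with both values, and a requirement that a light call hold against both dark groups. The procedures were tested on simulated data. For light in Col-0, 200 genes were planted at 4-fold, and 100% of the 154 with a level over 1 FPKM were listed. Of 200 random lists, drawn from genes listed in any simulated table, 1.5% had p under 0.05. For the difference of the light effect, 200 genes were planted at 4-fold. The 149 with a level over 1 FPKM and a value in every group were scored, and 100% reached 1. Simulated reads carried counting error only, so these shares do not test the spread between replicates. Reads were recovered whole for 99.4% of 1351 genes simulated for light in Col-0. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.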

Results

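RNA was sequenced from Arabidopsis thaliana seedlings grown for 4 days in the dark and then either kept dark or given 3 h of light, a treatment that starts de-etiolation, the switch from growth in darkness to photosynthetic growth. The wild type Col-0 was set beside 35S:miR396a, a line that expresses the microRNA miR396a from a strong viral promoter. The 12 libraries fall into 4 groups of 3 biological replicates each: dark Col-0, illuminated Col-0, dark 35S:miR396a and illuminated 35S:miR396a. The labels call the tissue hypocotyl. The files give each gene's expression only as the authors' mean FPKM over a group, so no SD or n stands beside the means, and the spread between replicates could not be compared with any difference. From the folds and p-values of the authors' deposited tables, the pooled depth was estimated at about 115000000 fragments for dark Col-0, 119000000 for illuminated Col-0, 119000000 for dark 35S:miR396a and 128000000 for illuminated 35S:miR396a. "Listed" means called by the authors at over 2-fold, with a p-value that carries counting error only. Counts below are out of all members of a gene list. Tests of a share used only members listed in some table, such as 8 of 12 clock genes and 10 of 26 brassinosteroid genes. Positions are those of the TAIR10.1 annotation.

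The first question was whether the targets of miR396 were lower in the overexpressor. These are growth-regulating factors (GRFs), transcription factors that promote organ growth, and the transcription factor bHLH74. In the dark, 6 of the 8 targets were listed lower in 35S:miR396a than in Col-0, and none was listed higher. The 6 were GRF2, GRF4, GRF7, GRF8, GRF9 and bHLH74. Mean FPKM of GRF7 (AT5G53660, chromosome 5, 21794177 to 21796092) was 24.1 in dark Col-0 and 3.21 in dark 35S:miR396a, and that of bHLH74 (AT1G10120, chromosome 1, 3304039 to 3306956) was 17.5 and 3.61. GRF1 and GRF3 were not listed in the dark, with mean FPKM of 9.38 and 13.1 in Col-0 and 5.99 and 7.06 in 35S:miR396a. More targets were listed in the dark than expected from all 11417 genes listed in any table (75% against 19.3%, Fisher's exact test across genes, two-sided, adjusted p = 0.00623), while the lean toward lower values was not past the threshold (adjusted p = 0.0926). With only genes that had a value in both groups as background, a choice made after seeing the data, the share was not past the threshold either (same exact test, adjusted p = 0.0768).

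In the light, 6 of the 8 targets were again listed lower in 35S:miR396a and none higher, but these were GRF1, GRF2, GRF3, GRF4, GRF9 and bHLH74. GRF4 (AT3G52910, chromosome 3, 19615977 to 19618507) had a mean FPKM of 3.58 in illuminated Col-0 and 0.323 in illuminated 35S:miR396a, and GRF2 (AT4G37740, chromosome 4, 17725337 to 17727909) had 4.70 and 0.67. GRF7 and GRF8 were near 0.2 FPKM in both illuminated groups and were not listed between them: GRF7 was at 0.186 in Col-0 and 0.23 in 35S:miR396a. The direction split of the listed targets differed from that of other listed genes (Fisher's exact test across genes, two-sided, adjusted p = 0.0185), and their share did not (adjusted p = 0.858). Among the other members of the module, GRF6, which lacks the miR396 site, was listed lower in both conditions, with a log2 fold of −3.16 in the dark and −3.14 in the light in the authors' deposited tables. GIF1, a coactivator that binds GRFs, was listed higher in both, at 8.80 FPKM in dark Col-0 against 22.5 in dark 35S:miR396a and 5.79 against 17.3 in the light. MIR396A, MIR396B, GRF5, GIF2 and GIF3 were in no table, and the level of the microRNA itself was not analysed here.

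The next question was what light did in wild-type seedlings. Nuclear genes of the photosynthetic apparatus rose together in Col-0: 27 of 28 photosystem and Rubisco genes and 21 of 23 light-harvesting antenna genes were listed higher after 3 h of light, and none lower. RBCS1B, a small subunit of the carbon-fixing enzyme Rubisco, went from 182 to 3679 FPKM. LHCB1.1, a chlorophyll-binding antenna protein, went from 45.9 to 3303 FPKM (an FPKM ratio of 72.0), and the photosystem I subunit PSAH2 from 99.5 to 1264. The fold of LHCB1.1 in the authors' deposited table was 126, the only one of 2055 listed genes with over 5 FPKM in both groups that lay over 1.5 times from its FPKM ratio. Of the 29 tetrapyrrole genes, which make chlorophyll and heme, 18 were listed higher, among them CHLH, a magnesium chelatase subunit, from 83.5 to 555 FPKM, and 4 lower (HEMA2, PORA, PORB and FC1). PORA (AT5G54190, chromosome 5, 21990864 to 21992814), the protochlorophyllide reductase of dark-grown seedlings, went from 849 to 5.93 FPKM.

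Flavonoid genes, whose products absorb ultraviolet light, were listed higher for 14 of 19 members and lower for none. DFR and LDOX, which act late in anthocyanin synthesis, went from 0.04 to 32.9 and from 0.043 to 33.1 FPKM. Auxin genes went the other way, with 19 of 27 listed lower and 1, GH3.6, higher. IAA19, a repressor of auxin response, went from 100.5 to 9.15 FPKM. In the cell-wall expansion list 13 of 25 were listed lower and 4 higher (EXPA1, EXPA10, XTH16 and XTH31), and XTH15, an enzyme that remodels xyloglucan, went from 2402 to 39.0 FPKM. Of 26 brassinosteroid genes, 4 were listed lower (CPD, SOB7, IBH1 and PRE5), with the biosynthetic enzyme CPD at 143.5 and 52.5 FPKM, and 2 were listed higher, BEE2 and BEE3, transcription factors that promote growth.

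Of 18 oxidative-stress markers 12 were listed lower after light in Col-0 and none higher, and WRKY40, a transcription factor of stress and defence, went from 114 to 2.35 FPKM. The rapid touch and wound genes, a list added after the data were seen, moved the same way, with 20 of 20 listed lower. In the list of jasmonate and defence genes 11 of 19 were listed lower and 3 higher (LOX2, AOC2 and PR5), and JAZ7, a repressor of jasmonate signalling, went from 48.2 to 1.31 FPKM. Heat-shock genes were listed lower for 5 of 10 (HSFA2, HSP101, HSP70-4, HSP90.1 and HSP22) and higher for 1 (HSP18.2). Gibberellin and ethylene genes were listed lower for 10 of 19 and higher for 3 (GA20OX2, GA3OX1 and GA3OX2), and clock genes lower for 4 of 12 (CCA1, LHY, PRR9 and RVE8) and higher for 1 (ELF4). Light-signalling genes were listed lower for 10 of 35 and higher for 8, and antioxidant genes higher for 3 of 24 (GPX7, VTE1 and 2CPB) and lower for none. Of the miR396 targets GRF7 and GRF8 were listed lower, GRF4 was listed higher, and GRF6 of the wider module was listed lower. The photoreceptor PHYA, named after its values were seen, went from 287 to 53.2 FPKM. Seed-reserve markers were low and were listed higher for 6 of 9, with the storage protein CRC at 0.603 and 3.61 FPKM. Shoot-apex markers were listed higher for 2 of 8 (CUC1 and CUC2), root markers lower for 1 of 9 (RHD6), and cell-cycle genes in neither direction for any of 16.

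Across all genes, the authors' deposited table listed 4923 between dark and illuminated Col-0, 1945 higher and 2978 lower after light. DIR1 (AT5G48485, chromosome 5, 19646028 to 19646840), a lipid-transfer protein of systemic resistance, was listed at 0 in the dark and at 175 FPKM in the light. AT5G51190, an ERF transcription factor, was at 59.0 FPKM in the dark and listed at 0 in the light. By Fisher's exact test across genes (two-sided, adjusted over 80 tests), the share of listed members was above that of the background for photosystem and Rubisco (adjusted p = 8.62e-08), antenna (3.66e-05), tetrapyrrole (0.00033), auxin (0.00411), jasmonate and defence (0.0115), flavonoid (0.0168) and cell-wall genes (0.0217), and not past the threshold for oxidative-stress (0.124) and seed-reserve genes (0.311). By the same exact test, the split between higher and lower differed from that of other listed genes for photosystem and Rubisco (adjusted p = 8.78e-10), antenna (8.05e-08), flavonoid (2.38e-05), tetrapyrrole (0.000635), auxin (0.005), seed-reserve (0.0144) and oxidative-stress genes (0.0176), and not for cell-wall (0.37), jasmonate and defence (0.432), heat-shock (0.582) and brassinosteroid genes (1). With only genes that had a value in both groups as background, the shares of auxin (adjusted p = 0.167 by the exact test), flavonoid (0.194), cell-wall (0.284) and jasmonate and defence genes (0.308) were not past the threshold, and neither were those of auxin (1) and cell-wall genes (0.181) at 4-fold. Dark Col-0 also stood apart from dark 35S:miR396a in stress genes. When only genes listed the same way against both dark groups were kept, a choice made after seeing the data, 3241 remained, with 3 oxidative-stress markers lower (AATP1-like, ERF5 and RBOHC), 1 heat-shock gene lower (HSP22) and 1 higher (HSP18.2), and 1 seed-reserve marker higher (SESA1). In the jasmonate list 2 were then higher (LOX2 and AOC2) and none lower, the reverse of the count above, and light-signalling genes also turned, with 8 higher and 7 lower. The added dark group, dark 35S:miR396a, differs in genotype as well as light. In it 14 of 19 jasmonate genes were already listed lower than in dark Col-0. Their loss under this choice therefore does not show that light left them unchanged in Col-0. The log2 ratio of all 7778 genes with values in both groups had a median of −0.11.

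**Figure D1:**
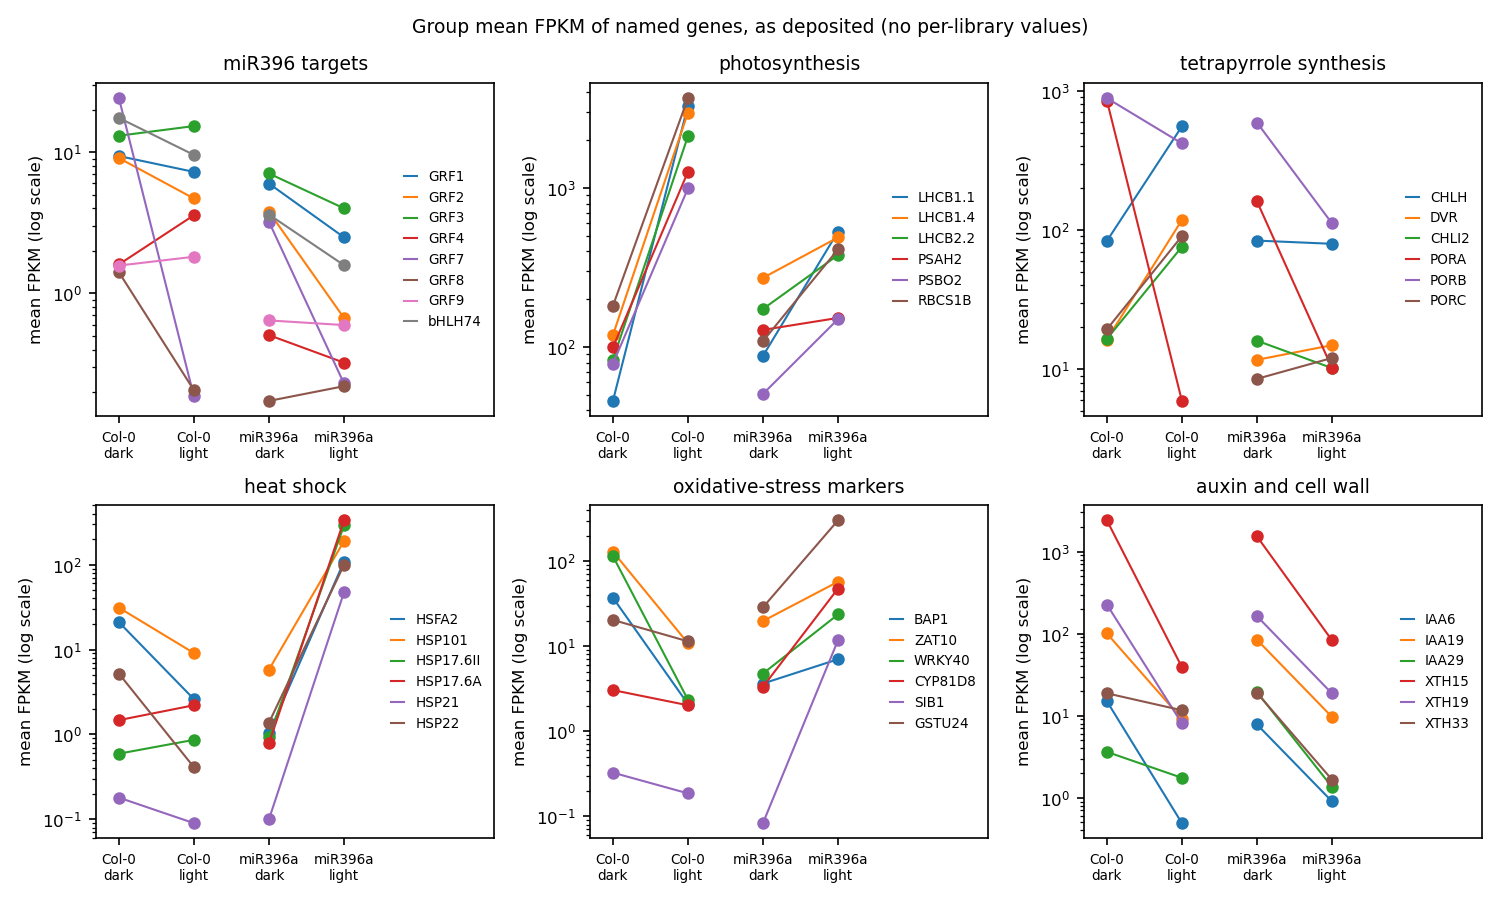
Group mean FPKM (log scale) of named genes in dark and illuminated Col-0 and 35S:miR396a, each point being the authors' mean over a group and each line joining dark to light within a genotype, with no error bars because per-library values were not used. RBCS1B climbs from 182 to 3679 in Col-0 and from 109 to 411 in 35S:miR396a. In 35S:miR396a it was 1 of only 2 of 28 photosystem and Rubisco genes listed higher, with 3 lower and 23 not listed. Heat-shock genes such as HSFA2 climb in 35S:miR396a, from 1.03 to 109.

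The same light treatment was then compared in 35S:miR396a. Heat-shock and jasmonate genes rose there. All 10 heat-shock genes were listed higher after light, among them HSP17.6A, a small heat-shock protein, from 0.783 to 332 FPKM, and the chloroplast small heat-shock protein HSP21 from 0.1 to 47.1. Oxidative-stress markers were listed higher for 12 of 18 and lower for 1, EX2. The detoxifying enzyme GSTU24 went from 28.6 to 301 FPKM and SIB1, a sigma factor binding protein of defence, from 0.083 to 11.7. Jasmonate and defence genes were listed higher for 13 of 19 and lower for none, with the tyrosine aminotransferase TAT3 going from 0.093 to 13.8 FPKM. Of the 20 rapid touch and wound genes 8 were listed higher and 1, EXO, lower.

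Few photosystem, Rubisco and tetrapyrrole genes were listed in 35S:miR396a. Of the 28 photosystem and Rubisco genes 2 were listed higher (PSBO2 and RBCS1B) and 3 lower (PSAH1, RBCS1A and RBCS2B), and of 23 antenna genes 6 were listed higher and 3 lower (LHCA2, LHCB1.3 and LHCB4.2). RBCS1B went from 109 to 411 FPKM and LHCB1.1 from 88.0 to 532 (an FPKM ratio of 6.04, against a fold of 9.64 in the authors' deposited table), while PSAH2, not listed, was at 128 in the dark and 153 in the light. Among tetrapyrrole genes 1 was listed higher, the ferrochelatase FC1 of heme synthesis, and 4 lower (PORA, PORB, CHLM and CHLP). PORA went from 161 to 10.2 FPKM and PORB, a protochlorophyllide reductase, from 591 to 112. CHLH, not listed, was at 83.9 in the dark and 79.6 in the light. The ELIP1 and ELIP2 proteins, which protect against excess light, were among the higher antenna genes, and ELIP1 went from 2.57 to 172 FPKM.

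Auxin genes fell in 35S:miR396a, listed lower for 21 of 27 and higher for none. Cell-wall expansion genes were listed lower for 12 of 25 and higher for none, with XTH15 going from 1534 to 83.1 FPKM, and the auxin gene IAA29 went from 19.5 to 1.36. Brassinosteroid genes were listed lower for 7 of 26 and higher for none, among them BR6OX1, a biosynthetic oxidase, from 2.75 to 0.436 FPKM, and the growth-promoting PRE1 and PRE6. Flavonoid genes were listed higher for 11 of 19 and lower for 1, MYB111. Light-signalling genes were listed higher for 11 of 35 and lower for 8, and clock genes higher for 5 of 12 (PRR9, PRR5, ELF4, GI and RVE1) and lower for 1 (LHY). Gibberellin and ethylene genes were listed higher for 4 of 19 (GA3OX2, GA2OX1, GA2OX2 and ERF1) and lower for 8, and antioxidant genes higher for 6 of 24 and lower for 2 (TAPX and FSD2). APX2, a stress-induced ascorbate peroxidase at 0.05 FPKM in the dark, rose by a log2 fold of 8.43 in the authors' deposited table. Of the 8 miR396 targets 4 were listed lower, GRF1, GRF2, GRF7 and bHLH74, and GRF6 of the wider module was listed lower. Seed-reserve markers were listed higher for 7 of 9, with SESA3 at 1.48 and 23.0 FPKM. Cell-cycle genes were listed lower for 2 of 16 (CYCA2;3 and MCM2), root markers higher for 1 of 9 (PYK10), and shoot-apex markers in neither direction.

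The authors' deposited table listed 4984 genes between dark and illuminated 35S:miR396a, 2352 higher and 2632 lower after light. At 4-fold or more the split was 1047 higher and 718 lower. DIR1, listed at 0 in the dark, was at 23.6 FPKM in the light, and AT3G05730, which encodes a defensin-like protein, went from 292 to 2.56 FPKM. The sugar alcohol transporter PMT6 went from 13.2 FPKM to a value listed at 0. By Fisher's exact test across genes, more members than in the background were listed for auxin (adjusted p = 0.00171), heat-shock (0.002), light-signalling (0.0426) and jasmonate and defence genes (0.0426), and fewer for photosystem and Rubisco (0.0277) and tetrapyrrole genes (0.0487). The share was not past the threshold for oxidative-stress (0.0506), seed-reserve (0.112), flavonoid (0.125), brassinosteroid (0.196), cell-wall (0.538) and antenna genes (0.94). With only genes that had a value in both groups as background, it was not past the threshold for auxin (adjusted p = 0.0854 by the exact test), heat-shock (0.0854), light-signalling (0.231) and jasmonate and defence genes (0.389), and with all annotated genes it was not for photosystem and Rubisco (0.511) and tetrapyrrole genes (0.514). The heat-shock share could not be higher, since all 10 were listed. By the same exact test, the split between higher and lower differed from that of other listed genes for auxin (adjusted p = 2.00e-05), jasmonate and defence (0.000537), heat-shock (0.00371), cell-wall (0.00371), oxidative-stress (0.00613), flavonoid (0.00986), seed-reserve (0.0179) and brassinosteroid genes (0.0451). When only genes listed the same way against both dark groups were kept, 3351 remained, with all 10 heat-shock genes still higher, 6 oxidative-stress markers higher and 1 lower (EX2), and 3 jasmonate and defence genes higher (AOC2, VSP2 and TAT3). Light-signalling genes then turned, with 6 higher and 8 lower.

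The responses of the genotypes to light were then set side by side. Both light tables listed 2012 genes, of which 520 were higher after light in both genotypes and 857 lower in both. Another 488 were lower in Col-0 and higher in 35S:miR396a, and 147 the reverse. Auxin genes stood among those that fell in both (15 of the 15 listed in both tables), and flavonoid genes among those that rose in both (9 of 9). Oxidative-stress markers were lower in Col-0 and higher in 35S:miR396a for 8 of the 8 listed in both tables, jasmonate and defence genes for 9 of 10 and heat-shock genes for 5 of 6. When each light call had to hold against both dark groups, a choice made after seeing the data, 61 genes were lower in Col-0 and higher in 35S:miR396a and 36 the reverse, with none of the oxidative-stress or jasmonate genes and 1 heat-shock gene, HSP22, among them. The dark group of the other genotype differs in genotype as well as light, so this choice also removes genes that differ between the dark groups. With lists of those sizes drawn independently from the 11417 genes listed in any table, 401 would be shared upward and 687 downward, and with all 38095 annotated genes as background 120 and 206. No such value was computed for the opposite calls, so their counts are not shown to be an excess.

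**Figure D2:**
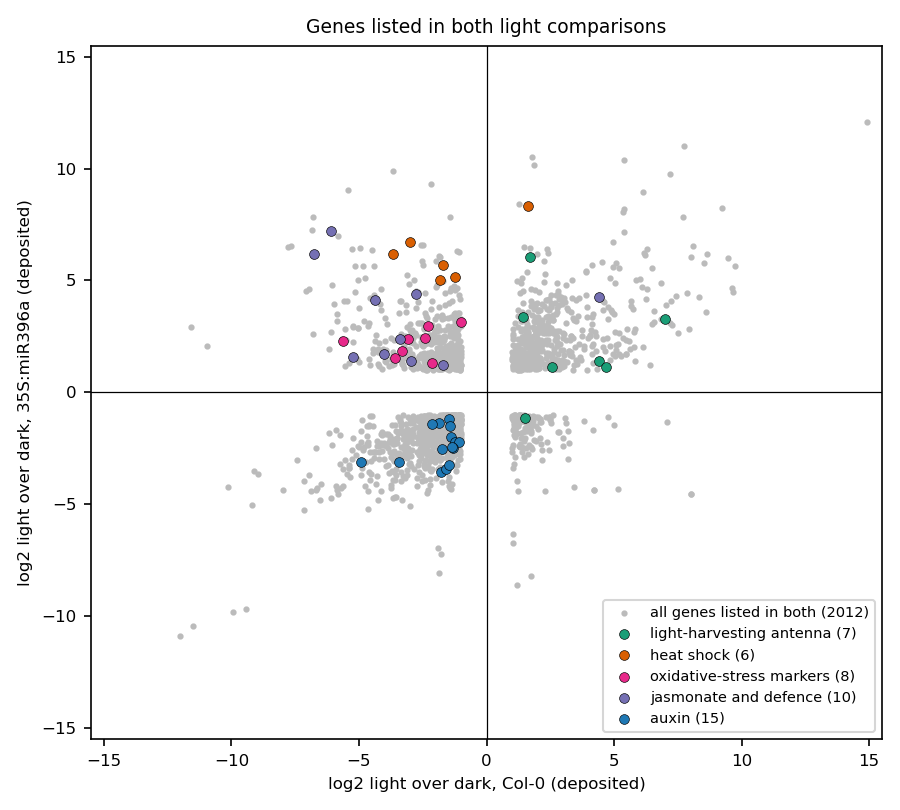
Log2 light over dark in Col-0 (x axis) and in 35S:miR396a (y axis), from the authors' deposited tables, for the 2012 genes listed in both, with members of 5 gene lists in colour. The 15 auxin genes lie in the lower left corner, and the 8 oxidative-stress markers lie in the upper left corner, lower in Col-0 and higher in 35S:miR396a.

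For 6223 genes with a value in every group, the log2 light effect in 35S:miR396a minus that in Col-0, on the log2(FPKM + 1) scale, was 1 or more for 1763 genes and −1 or less for 1417. Photosystem and Rubisco genes had a median difference of −2.47, with 28 of 28 at −1 or less, antenna genes −2.40 with 21 of 23, and tetrapyrrole genes −2.02 with 19 of 22. Heat-shock genes had a median difference of 7.02, with 10 of 10 at 1 or more, oxidative-stress markers 4.12 with 14 of 14, and jasmonate and defence genes 3.61 with 13 of 16. The largest positive differences among well-expressed genes were those of AT1G76640, a calmodulin-like protein (10.29), HSFA2, a heat-shock transcription factor (8.36), and the glutaredoxin GRX480 (8.36). The largest negative ones were those of AT3G16670 (−7.60), AT3G16660 (−6.13) and AT3G05730 (−5.98). These are values from group means, and the difference itself was not tested. It also holds the gap between the dark groups. For jasmonate and defence genes, the median log2 fold of listed members in 35S:miR396a over Col-0 was −2.89 in the dark and 1.90 in the light. It was −1.91 and 3.11 for oxidative-stress markers and −2.73 and 6.74 for heat-shock genes. AT1G76640 and GRX480 had log2 folds of −5.50 and −4.33 in the dark.

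The genotypes were next compared within the dark. Oxidative-stress and jasmonate genes were lower in dark 35S:miR396a than in dark Col-0. Of 19 jasmonate and defence genes 14 were listed lower and 1, LOX2, higher. The jasmonate biosynthesis gene LOX3 was at 8.76 FPKM in Col-0 and 0.166 in 35S:miR396a. Oxidative-stress markers were listed lower for 11 of 18 and higher for none, with ZAT10, a stress-induced zinc-finger repressor, at 129 and 19.7 FPKM. Heat-shock genes were listed lower for 5 of 10 (HSFA2, HSP101, HSP70-4, HSP90.1 and HSP22) and higher for none, and HSFA2 was at 21.0 and 1.03 FPKM. Rapid touch and wound genes, a list made after the pattern was seen, were listed lower for 19 of 20.

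Light-signalling genes were listed lower for 10 of 35, among them HY5, a transcription factor that promotes de-etiolation, with a log2 fold of −1.82 in the authors' deposited table, and higher for 1, PIL1. Clock genes were listed lower for 5 of 12 (PRR9, PRR5, ELF4, GI and RVE1), with PRR9 at 9.32 and 1.00 FPKM. Chlorophyll precursors are made in the dark up to protochlorophyllide, and 4 of 29 tetrapyrrole genes were listed lower: PORA, at 849 and 161 FPKM, PORC, FC1, and FLU, a negative regulator of the pathway, at 85.2 and 24.8 FPKM. None of the 28 photosystem and Rubisco genes was listed. Antenna genes were listed higher for 3 of 23 (LHCB1.1, LHCB1.4 and LHCB2.2) and lower for 2 (ELIP1 and ELIP2). Of 26 brassinosteroid genes 2 were listed higher, BEE3 and PRE6, and 1 lower, PRE5, with PRE6 at 24.6 and 52.5 FPKM. Flavonoid genes were listed lower for 5 of 19 (F3H, UGT78D2, MYB12, MYB111 and MYB75), with the anthocyanin regulator MYB75 at 3.08 and 0.14 FPKM. Antioxidant genes were listed higher for 1 of 24 (CSD2) and lower for 2 (FSD1 and VTC2), and auxin genes higher for 1 of 27 (IAA29) and lower for 1 (IAA5). Cell-wall genes were listed higher for 1 of 25 (EXPA1) and lower for 3 (XTH9, XTH22 and XTH23), and gibberellin and ethylene genes higher for 3 of 19 (GA20OX2, ACS8 and EBF2) and lower for 4 (GA2OX1, GA2OX2, ACS6 and ERF1). No cell-cycle gene was listed.

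Seed-reserve markers were higher in dark 35S:miR396a for 8 of 9, with the storage globulin CRA1 at 0.953 FPKM in Col-0 and 14.3 in 35S:miR396a and the oil-body protein OLEO2 at 0.593 and 4.42. Shoot-apex markers were listed higher for 3 of 8 (CLV3, CUC1 and CUC2, all under 1 FPKM) and root markers for 2 of 9 (PRP3 and LRX1). In all, the authors' deposited table listed 2207 genes in the dark, 998 higher and 1209 lower in 35S:miR396a. AT4G29200 was at 20.1 FPKM in dark Col-0 and 0.033 in dark 35S:miR396a. CYP71A12, a cytochrome P450 of camalexin synthesis, was at 0.41 and 17.9 FPKM. Fisher's exact test across genes gave an adjusted p of 8.62e-08 for jasmonate and defence genes, 0.00023 for seed-reserve markers, 0.00122 for oxidative-stress markers, 0.034 for clock genes and 0.0463 for light-signalling genes, each with more members listed than the background, and 0.0168 for photosystem and Rubisco genes, with fewer. For heat-shock genes it was 0.0815. With only genes that had a value in both groups as background, clock (adjusted p = 0.114 by the exact test) and light-signalling genes (0.389) were not past the threshold, and neither were photosystem and Rubisco genes with all annotated genes as background (0.511). None of those photosystem and Rubisco genes was listed, so their share could not be lower. By the same exact test, the split between higher and lower was past the threshold for oxidative-stress (adjusted p = 0.00741), seed-reserve (0.00818), jasmonate and defence (0.0114) and light-signalling genes (0.0437). With FPKM ratios on the log2(FPKM + 1) scale 1040 of these genes passed 2-fold, 308 higher and 732 lower.

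**Figure D3:**
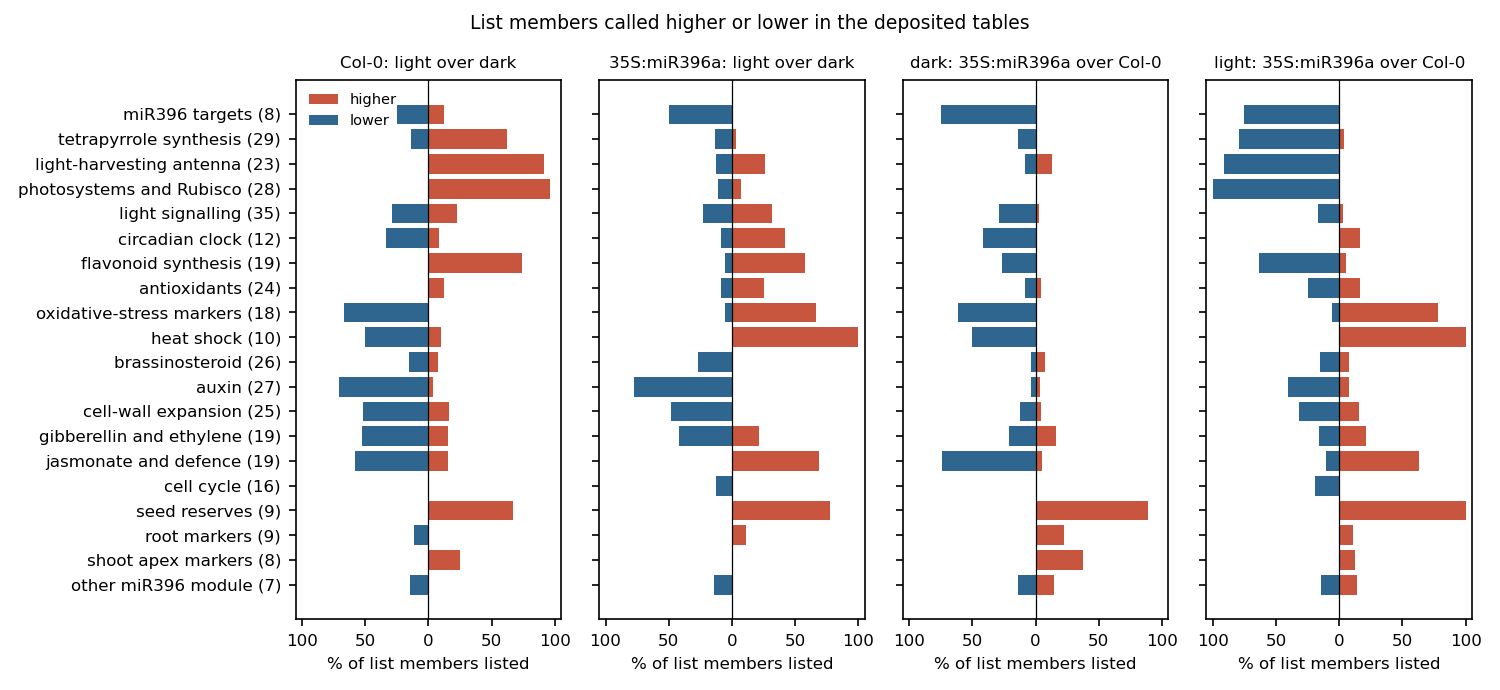
Share of each gene list (x axis, percent of members, with the number of members in brackets) listed higher (right) or lower (left) in the authors' deposited tables for each of the 4 main comparisons. Photosystem and Rubisco genes are listed higher for 27 of 28 in illuminated Col-0 and lower for 28 of 28 in illuminated 35S:miR396a against illuminated Col-0.

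The last comparison was that of the genotypes in the light. Photosynthesis genes were lower in illuminated 35S:miR396a than in illuminated Col-0: 28 of 28 photosystem and Rubisco genes, 21 of 23 antenna genes and 23 of 29 tetrapyrrole genes were listed lower. PSAH2 was at 1264 FPKM in Col-0 and 153 in 35S:miR396a, LHCB2.3 at 855 and 81.6, and the chlorophyll synthesis reductase DVR at 118 and 14.9. The one tetrapyrrole gene listed higher was FC1. Flavonoid genes were listed lower for 12 of 19 and higher for 1, MYB12, with the flavonol synthase FLS1 at 48.3 and 1.85 FPKM. CHS, the first enzyme of flavonoid synthesis, named after its values were seen, was at 326 and 19.7 FPKM. GLK1, GNC and CGA1, transcription factors of chloroplast development, were among the 6 of 35 light-signalling genes listed lower, and HY5 was the 1 listed higher.

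Heat-shock and oxidative-stress genes were higher in illuminated 35S:miR396a. All 10 heat-shock genes were listed higher, with HSP17.6II at 0.863 FPKM in Col-0 and 289 in 35S:miR396a. Oxidative-stress markers were listed higher for 14 of 18 and lower for 1, EX1, a plastid protein needed for singlet-oxygen signalling. Jasmonate and defence genes were listed higher for 12 of 19 and lower for 2 (LOX2 and AOC2). Antioxidant genes were split, 4 of 24 higher (APX1, APX2, CSD1 and CSD2) and 6 lower. APX2, at 0.11 FPKM in illuminated Col-0, was higher by a log2 fold of 7.33 in the authors' deposited table. The copper/zinc superoxide dismutase CSD2 was at 55.7 and 129 FPKM, while the thylakoid ascorbate peroxidase TAPX was at 38.1 and 8.65. Seed-reserve markers were listed higher for 9 of 9, with the seed storage albumin SESA2 at 2.99 and 24.7 FPKM. Of genes encoded in the mitochondrion, looked at after the data were seen, 54 were listed higher and 3 lower (ATMG00210, ATMG00290 and ATMG00590), and of the 20 rapid touch and wound genes 12 were listed higher and 1, EXO, lower.

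Auxin genes were listed lower in the light for 11 of 27 and higher for 2 (GH3.1 and GH3.3), with SAUR63 at 5.74 and 1.16 FPKM. Cell-wall genes were listed lower for 8 of 25 and higher for 4 (XTH5, XTH15, XTH18 and XTH19), and XTH33 was at 11.6 and 1.66 FPKM. Of 26 brassinosteroid genes 4 were listed lower (BR6OX1, PRE1, BEE2 and BEE3) and 2 higher (SOB7, a brassinosteroid-inactivating enzyme, and IBH1, a growth repressor), with BEE2 at 33.9 and 7.27 FPKM. Cell-cycle genes were listed lower for 3 of 16 (CYCA2;3, MCM2 and MCM5), and gibberellin and ethylene genes higher for 4 of 19 (ACS8, ERF1, EBF2 and ETR2) and lower for 3 (GA20OX1, GA3OX1 and GA2OX1). Clock genes were listed higher for 2 of 12 (CCA1 and PRR9), root markers higher for 1 of 9 (LRX1) and shoot-apex markers for 1 of 8 (CLV3).

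The authors' deposited table listed 7004 genes between the genotypes in the light, 4051 higher and 2953 lower in 35S:miR396a, and the log2 ratio of all 8798 genes with values in both groups had a median of 0.19. FdC1, a ferredoxin-like protein, was at 130 FPKM in Col-0 and listed at 0 in 35S:miR396a. Fisher's exact test across genes found more members listed than in the background for photosystem and Rubisco (adjusted p = 3.66e-05), tetrapyrrole (0.0055), antenna (0.0115), heat-shock (0.034) and seed-reserve genes (0.0487), and fewer for light-signalling genes (0.00122). The share was not past the threshold for oxidative-stress (0.154), auxin (0.375) and flavonoid genes (0.596). By the same exact test, the split between higher and lower was past the threshold for photosystem and Rubisco (adjusted p = 1.11e-09), antenna (2.42e-07), tetrapyrrole (4.90e-07), flavonoid (0.00188), auxin (0.012), oxidative-stress (0.0205), heat-shock (0.0206) and seed-reserve genes (0.0374), and not for jasmonate and defence (0.132), cell-wall (0.26) and brassinosteroid genes (0.409). With only genes that had a value in both groups as background, the shares of tetrapyrrole (adjusted p = 0.147 by the exact test), antenna (0.389), seed-reserve (0.408) and heat-shock genes (0.418) were not past the threshold, and fewer auxin genes were listed than in the background (0.0319). All 9 seed-reserve and all 10 heat-shock genes were listed, so their shares could not be higher. With 7004 of 8798 background genes listed, lists that small could not pass. The low share of light-signalling genes was not past the threshold with all annotated genes as background (0.771). Near-identical copies (LHCB1.1 to LHCB1.5, RBCS1B, RBCS2B and RBCS3B, SAUR19 to SAUR24, the small heat-shock genes and the SESA genes) share reads in a way the files do not describe, so the values of single copies are uncertain.

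The genotype tables listed 1315 genes in both dark and light. Of these 462 were higher in 35S:miR396a in both and 217 lower in both, with bHLH74, GRF2, GRF4, GRF6 and GRF9 among the lower ones. Another 530 were lower in the dark and higher in the light, the pattern of WRKY40, HSFA2 and JAZ8, and 106 the reverse. Independent lists of these sizes among the 11417 listed genes would share 354 upward and 313 downward, so the observed downward overlap was below that value, and among all 38095 annotated genes 106 and 93.7, so it was above it. The opposite counts were not set beside such values.

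The remaining tables cross genotype and light. Between dark Col-0 and illuminated 35S:miR396a the authors' deposited table listed 5601 genes, 2691 higher and 2910 lower in the latter, and between illuminated Col-0 and dark 35S:miR396a 5414, 3371 higher and 2043 lower in dark 35S:miR396a. In the authors' deposited tables the log2 fold of each crossing comparison equalled the sum of its parts within 0.01 for 946 of 946 and 466 of 466 genes listed in the tables concerned, as it must when all rest on the same counts.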

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

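The tests of a freed share of the library, of stray light and of touch genes in the light were chosen after the results were seen; the test of touch genes in the dark was written before its own result but after the pattern was seen. Genes called in opposite directions by light in the genotypes drew attention. There were 488 listed lower in Col-0 and higher in 35S:miR396a, and 147 the reverse. Together these were 635 of the 2012 genes listed in both light tables (31.6%). They were not set beside the counts of independent lists, so an excess of opposite calls is not shown. Within the gene lists, opposite calls covered 8 oxidative-stress markers, 5 heat-shock genes (HSFA2, HSP101, HSP70-4, HSP90.1 and HSP22) and 9 jasmonate and defence genes. When each call had to hold against both dark groups these counts were 61 and 36 over all genes, and within those lists the opposite call was left for HSP22 alone. The difference itself was not tested, because only group averages were used, and for the same reason no library was examined for standing apart from its group.

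Heat-shock and oxidative-stress genes were higher in illuminated 35S:miR396a than in illuminated Col-0. A candidate explanation is that fewer photosynthesis transcripts freed a share of the library for all others. But the median log2 ratio was 0.19 over the 8798 genes with values in both light groups. It was 0.027 over the 1794 of these not listed in this comparison. The median of the 10 heat-shock genes was 6.74, with HSP70-4, the lowest of them, 9.86-fold higher in the authors' deposited table. A freed share of the library thus does not account for them. Touch or wounding of illuminated 35S:miR396a at harvest may contribute. Of the 20 rapid touch and wound genes, 12 were listed higher there and 1 (EXO) lower, against 35.5% of all listed genes higher. Touch genes were also high in dark Col-0, where 19 of 20 lay above dark 35S:miR396a. Yet all 10 heat-shock genes were listed higher in illuminated 35S:miR396a than in both dark groups. Of 18 oxidative-stress markers 6 were higher and 1 (EX2) lower against both. A touch response like that of dark Col-0 therefore does not by itself account for the heat-shock genes. The 9 seed-reserve markers (median log2 2.98) and 54 mitochondrial genes against 3 were higher as well. These sets do not speak for touch. They were also higher in dark 35S:miR396a (8 of 9, and 18 against 1), where 19 of 20 touch genes were lower. Handling, the replicate spread and an effect of the genotype, which was not tested apart from them, stay open.

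Stress and jasmonate genes were higher in dark Col-0 than in dark 35S:miR396a. Stray light on dark Col-0 could raise light-induced genes such as ELIP1, at 56.8 FPKM in dark Col-0 and 2.57 in dark 35S:miR396a. Of the 10 light-signalling genes listed lower in dark 35S:miR396a, 7 were higher after light in 35S:miR396a and none lower, which goes with stray light, while in Col-0 3 were higher (HYH, BBX25 and RUP2) and 3 lower (HY5, RUP1 and GLK2), and both counts shift with the dark levels by which these genes were chosen. Against it, the 51 photosystem, Rubisco and antenna genes had a median log2 of dark Col-0 over dark 35S:miR396a of −0.078 (quartiles −0.36 and 0.20), and PORA, lower after light, was at 849 and 161 FPKM, so stray light and the genotype cannot be told apart, because these values disagree. Touch or wounding of dark Col-0 at harvest would raise rapid touch and wound genes. In dark 35S:miR396a 19 of 20 of these (95%) were listed lower, against 10.6% of all listed genes. After light in Col-0, 20 of 20 were listed lower. But the touch response overlaps with other stress responses, and all dark Col-0 libraries share a genotype. Handling and an effect of the genotype therefore stay open, also for the lower values of stress, jasmonate and touch genes in Col-0 after light.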

How the results depend on the processing

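Requiring calls against both dark groups, at least 30 pooled reads, no organelle genes and a background of genes with both values were chosen after seeing the data. No paired analysis was possible because the tables hold group averages without replicate numbers; leaving out a replicate, other splits of the libraries, and the count tests planned for single libraries were not run for the same reason. At 4-fold the counts were 1684 (light, Col-0), 1765 (light, 35S:miR396a; 1047 higher and 718 lower, against 2352 and 2632), 713 (genotype, dark), 2372 (genotype, light), 1897 (dark Col-0 against illuminated 35S:miR396a; 1059 higher and 838 lower, against 2691 and 2910) and 1753 (illuminated Col-0 against dark 35S:miR396a), 448 (shared light effect) and 140 (shared genotype effect), since a stricter threshold keeps fewer genes. FPKM ratios with a pseudocount of 1 gave 3162, 2806, 1040 (308 higher and 732 lower, against 998 and 1209) and 4408 in the order of the main comparisons, since low genes shrink. The shared genotype effect was 446 genes at a q-value of 1e-10 and 386 with low values filtered. The difference of the light effect covered 1626 genes with a pseudocount of 10 and 1179 at 2 or more. List tests past the threshold numbered 49 with all annotated genes as background and 12 with genes that had both values. Calls against both dark groups numbered 3241 for Col-0 (1451 higher and 1790 lower, against 1945 and 2978) and 3351 for 35S:miR396a. Genes with opposite calls in the genotypes fell from 635 to 97, since each call must then pass another table. Directions of lists turned at 4-fold for light signalling in Col-0 (5 listed, 3 higher), gibberellin and ethylene in 35S:miR396a (5 listed, 3 higher) and antenna in the dark (2 listed, both lower), and against both dark groups for light signalling in Col-0 (15 listed, 8 higher) and in 35S:miR396a (14 listed, 8 lower) and for jasmonate and defence in Col-0 (2 listed, both higher); the cause was not tested. Of 427 named values, 60 no longer passed 2-fold with the pseudocount and 1 after recentring, and the rest kept their call. Other totals across all genes stayed within 1.5 times, but genes higher in dark 35S:miR396a fell from 998 to 611 at a q-value of 1e-10 and to 639 with low values filtered, and genes raised by light in both genotypes from 520 to 329 with low values filtered; genes lowered by light in 35S:miR396a fell from 2632 to 1745 against both dark groups. Counts of list members moved by over 1.5 times for 51 counts at 4-fold, 15 against both dark groups and 6 at a q-value of 1e-10. Few reads limit single low genes, and no setting measures the spread between replicates.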

Other observations

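The test of RNA selection was written before its result was seen, and the patterns themselves were noticed in the data. Genes encoded in the organelles, outside the fixed lists, were mostly listed higher in 35S:miR396a. In the dark 62 chloroplast genes were listed higher and 0 lower in the authors' deposited table, and in the light 25 and 0. For mitochondrial genes the counts were 18 higher and 1 lower (ATMG00210) in the dark and 54 higher and 3 lower (ATMG00210, ATMG00290 and ATMG00590) in the light. ATCG00490, which encodes the large subunit of Rubisco, had a mean FPKM of 4.09 in dark Col-0, 8.63 in illuminated Col-0, 11.4 in dark 35S:miR396a and 15.3 in illuminated 35S:miR396a. ATCG00120, which encodes a subunit of the chloroplast ATP synthase, had 8.85, 15.4, 47.1 and 28.8. Some chloroplast identifiers, such as ATCG00900 and ATCG01240, had equal values in every group, so these counts can hold copies. Many mitochondrial genes lay far under 1 FPKM in illuminated Col-0, such as ATMG00900, at 0.04 there and 0.376 in illuminated 35S:miR396a. ATMG00030 was at 9.50 and 129. After light 18 chloroplast genes were listed higher in Col-0 and 0 lower, while in 35S:miR396a 1 (ATCG00680) was listed higher and 10 lower. Of mitochondrial genes 0 were listed higher and 4 lower in Col-0 (ATMG01090, ATMG01170, ATMG01320 and ATMG01370), and 32 higher and 1 lower (ATMG00290) in 35S:miR396a.

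Organelle transcripts carry few poly(A) tails, so less strict selection of polyadenylated RNA in 35S:miR396a could raise them without a change in the seedlings. Such selection would also raise small nuclear, nucleolar, ribosomal and transfer RNA genes of the nucleus, and 0 of these were listed in either genotype table, too few for a decision. Whether selection or the genotype lies behind the higher organelle values in 35S:miR396a cannot be told apart, because too few such RNAs were called. After light in 35S:miR396a, chloroplast genes were mostly listed lower (10 against 1) and mitochondrial genes mostly higher (32 against 1). Selection alone would move both sets the same way, so it does not by itself account for that change with light.

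DDF1, CBF2 and CML38 are named here after their values were seen. DDF1, an AP2 transcription factor, was at 57.8 FPKM in dark Col-0, 0.316 in illuminated Col-0, 0.22 in dark 35S:miR396a and 0.24 in illuminated 35S:miR396a. CBF2, a cold-response regulator with near-identical neighbours, was at 120, 2.64, 8.06 and 5.97 FPKM. CML38, a calmodulin-like protein, was at 83.6, 4.12, 2.18 and 46.2 FPKM, high in dark Col-0 and again in illuminated 35S:miR396a.

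GRF7 fell with light in both genotypes, from 24.1 to 0.186 FPKM in Col-0 and from 3.21 to 0.23 in 35S:miR396a, while GRF3 was at 13.1 and 15.3 in Col-0 and at 7.06 and 4.0 in 35S:miR396a. In illuminated Col-0 GRF7 was near its level in the illuminated overexpressor.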
